A study of Mus musculus with 4 samples.

How the data were processed

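Methylated DNA was measured by MeDIP-seq, in which sheared genomic DNA is pulled down with an antibody against 5-methylcytosine and the recovered fragments are sequenced. Per the labels' protocols, ICR mice, an outbred strain, were used. Male founders received a high-fat diet with 33% of energy as fat until 12 weeks of age and then a low dose of streptozotocin, which damages insulin-producing beta cells, and those with a fasting glucose of 7 to 11 mM over the following 4 weeks were taken as the T2D (type 2 diabetes model) group. Control founders received a control diet. Founders were mated at 16 weeks of age with females on standard diet. Pancreatic islets came from 6 offspring of control and 6 offspring of T2D fathers at 3 weeks of age, and sperm from 6 control and 6 T2D founders at 16 weeks, after a somatic cell lysis step. For each of these 4 groups 1 library was available, and the labels do not say how the animals were combined. Libraries were amplified with 15 PCR cycles and size-selected at about 250 bp including adapters.

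The authors deposited 1 peak list per library. A peak is an interval in which reads are denser than the local background. The submitters' processing notes name the mouse build mm9 and CASAVA 1.4. Per the file headers of both sperm lists, peaks were called with MACS on 49 bp reads without a control library, at a p-value threshold of 1.00e-05, with a band width of 200 bp, a model fold of 10 to 30, an effective genome size of 2.65e+09 bp, a local background taken over 5000 bp and at most 2 reads kept per position. The islet lists carry the same 8 columns without header comments, so their caller and settings are not given in the sources used here. Without an input control, local differences in copy number or mappability are not removed from the peaks. Each list gives, per the file headers, the peak's position and width in bp (start counted from 1), the deposited count of tags (sequenced reads) in the peak, a deposited score equal to 10 times the negative log10 of the caller's p-value, with a minimum of 50, and the deposited fold enrichment over the caller's background. The deposited tag counts are whole numbers and were not scaled to depth here. Enrichment and score are the authors' own values for each peak, relative to that library alone. They were used here to describe, rank or filter peaks within a list, except where a common cutoff of either was applied to all lists. Counts from such a cutoff are not on the same scale between libraries.

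Depth is stated for sperm only. Per the file headers, the control sperm library held 34094381 tags, 31053754 of them unique, and the T2D sperm library held 34926725 and 31833988. For islets the total was not stated. Part of the deposited enrichments in each list fall on a regular grid, as whole counts divided by a single background value would. The grid step, found in each list with a tolerance of 0.005, gave a background of 2.41 tags in the control and 2.45 tags in the T2D islet list, and 3.25 and 3.26 tags in the sperm lists. Between 18.9% and 23.5% of enrichments from 4 to 9 lay on the grid, against 2.41% to 2.55% for the median of the steps tried. For the sperm lists, unique tags times fragment length over genome size, from the headers, came to 3.26 and 3.27. By this estimate the background was nearly equal within each tissue and lower in islets than in sperm, but it does not give the depth of the islet libraries, whose fragment length in the caller is not given in the sources used here.

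Peaks of different lists were compared with bedtools 2.31.1. A peak had a partner where a peak of the other list overlapped it by at least 1 bp. The 1 bp overlap counts of all pairs of full lists were checked against an independent calculation in numpy 2.4.6. The overlap that placement alone gives was measured by shifting all peaks of a list around each chromosome by a random distance, 20 times per pair. The 4 lists were also merged into union regions. Within each tissue, a region was counted as present in both conditions, T2D only, control only or neither. Shares carry Wilson intervals and count ratios exact binomial intervals, all at 95%. Where a count was 0, the share it allows is given as 3 counts of the total, which is below the upper Wilson limit drawn in the figures. All of these cover counting error only, since PCR copies and neighbouring peaks are not independent. Each group had 1 library, so a difference between conditions within a tissue has no replicates, and no test over replicate libraries was made and no p-value is given. Shuffles of peaks between the lists of a tissue, used for windows along the genome, compare those libraries and not the conditions. Presence in only 1 list means that the other list holds no call there, not that methylation was shown to differ. The overlap and direction steps were tested on simulated lists made from 30515 sperm peak positions. With a planted chance of 60% that a region moved the same way in both tissues, 59.6% of the simulated regions did so and 59.6% was recovered, and with 50% the values were 50.2% and 50.2%. The simulated sites were kept well apart, moved only slightly between lists and had no missed calls. The simulation therefore checks the counting only. It does not show how missed weak calls or merged neighbours affect the share with the same direction.

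Gene-level comparisons were planned but not run. The gene table at hand is on GRCm38, whereas the lists are on mm9 and hold peaks on chromosome 1 up to position 197191647, beyond the last gene of that table at 195291439. Coordinates were not converted between builds, so no gene was assigned to a peak. No result is given for the promoter comparisons, the fixed lists of pathway, imprinted, germline and cell type genes, or Pik3r1, Pik3ca and Ptpn1, which had been set for reporting. Regions are therefore named by their mm9 coordinates. By a rule fixed before the data were examined, the named regions are, per tissue and direction, the 6 peaks of highest enrichment with no peak of the other condition within 1000 bp, with no limit on score. For regions with the same status in both tissues, the ranking fixed for genes, by the lower of the within-list enrichment percentiles, was carried over to regions, 6 per direction. The overlaps within and between tissues, the direction comparison and the shares by chromosome were also fixed then, as were the alternatives, namely a reciprocal overlap of 50%, a partner within 1000 bp, the best 50% of each list by score, equal list lengths, autosomes only, and an enrichment filter. The analyses by score, of peaks absent from the other tissue, of the strictest subset by direction, of X and Y ratios and of windows along the genome were chosen after the lists had been examined. Analyses used Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.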

Results

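MeDIP-seq peak lists were examined for pancreatic islets of 3-week-old offspring and for sperm of 16-week-old founder males, each with a T2D and a control library. The design asks whether diabetes in the father goes with differences in DNA methylation in his sperm and in the islets of his offspring. Each group had 1 library, so differences have no replicate check and their size is described without a test. The islet lists held 167712 peaks in the control and 167325 in the T2D library, which covered 161 Mb and 167 Mb. The sperm lists held 177342 and 178584 peaks and covered 195.8 Mb in each library. Median peak width was 865 bp and 898 bp in control and T2D islets, and 988 bp and 979 bp in control and T2D sperm. Median enrichment over background was 7.35 and 7.28 in islets and 6.77 and 6.75 in sperm. A peak held a median of 39 tags in either islet library and 50 tags in either sperm library. In sperm, peaks contained 35.6% of the unique tags in the control and 34.7% in the T2D library, and the corresponding share in islets is unknown because the total was not given.

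In islets, about equal numbers of peaks were specific to either condition. Of the T2D islet peaks, 67.3% (95% Wilson interval 67.1% to 67.5%) overlapped a control islet peak, which left 54677 peaks found in the T2D list only. Of the control islet peaks, 67.3% (67.1% to 67.5%) overlapped a T2D peak and 54850 were found in the control list only. The lists shared 99.1 Mb, or 43.2% of the bases covered by either. When T2D peaks were shifted to random positions on the same chromosomes, 12.4% to 13.2% overlapped a control peak. Peaks without a partner were the weaker ones of their list. In the T2D list they had a median enrichment of 6.80 and 29 tags, against 7.52 and 46 tags for matched peaks, and in the control list 6.74 and 29 tags against 7.66 and 45 tags.

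The share of islet peaks without a partner fell steadily with the caller's score. In the weakest 10% of the T2D list it was 58.7% (57.9% to 59.4%), in the strongest 10% 3.47% (3.21% to 3.76%), and among the strongest 1% it was 0.657%, or 11 of 1674 peaks. Among the strongest 0.1%, 0 of 168 peaks lacked a partner, which allows a share of up to 1.79%. The control islet list gave 58.8%, 3.26%, 0.715% and 0 of 168 peaks, the last with the same upper limit of 1.79%.

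**Figure D1:**
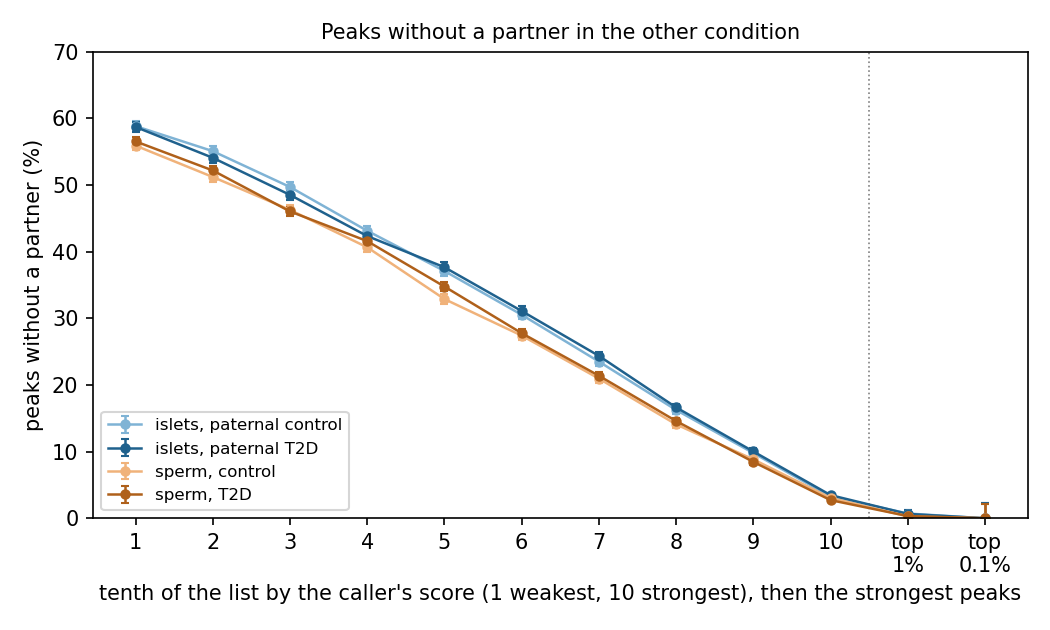
Percentage of peaks (y axis) with no overlapping peak in the other condition of the same tissue, by successive 10% of each list ranked on the caller's score (x axis), followed by the strongest 1% and 0.1%. Points are the 4 libraries and bars are 95% Wilson intervals for counting error; in each library the share falls from between 55.9% and 58.8% in the weakest 10% to between 2.72% and 3.47% in the strongest 10%.

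Some well-enriched islet regions nonetheless appeared in a single condition. With no partner allowed within 1000 bp, 552 T2D peaks and 512 control peaks of the strongest 10% remained. The 6 most enriched T2D-only regions had enrichments of 15.73 to 16.31 with 43 to 53 tags. The first lay on chromosome 17 from 18986534 to 18987464 (enrichment 16.31, 49 tags) and had no peak in either sperm library. The second, on chromosome 10 from 85230977 to 85231454 (16.20, 50 tags), also had a peak in control sperm. The third, on chromosome 7 from 35166833 to 35167374 (16.06, 43 tags), and the fourth, on chromosome 5 from 115482148 to 115482632 (15.88, 49 tags), had peaks in both sperm libraries. The others lay on chromosome 14 from 44281198 to 44281708 (15.81, 53 tags) and on chromosome 7 from 15378555 to 15379338 (15.73, 45 tags), where neither sperm library had a peak. The 6 most enriched control-only regions had enrichments of 16.23 to 17.76 with 40 to 57 tags. They were led by chromosome 7 from 32543552 to 32544065 (17.76, 48 tags) and chromosome 4 from 29644643 to 29645148 (17.26, 57 tags), both without a sperm peak. Next came 2 regions on X, from 31454673 to 31455125 (16.63, 40 tags, no sperm peak) and from 39549090 to 39549907 (16.47, 43 tags, peaks in both sperm libraries). The remaining regions, on chromosome 8 from 72734128 to 72734729 (16.28, 44 tags) and chromosome 3 from 34752192 to 34753079 (16.23, 51 tags), had peaks in both sperm libraries. Without an annotation on this build, the genes at these positions were not determined.

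Sperm of T2D and control fathers showed the same picture at a slightly higher overlap. Of the T2D sperm peaks, 69.4% (69.2% to 69.6%) overlapped a control peak and 54631 did not. Of the control sperm peaks, 69.9% (69.7% to 70.1%) overlapped a T2D peak and 53407 did not. The lists shared 122 Mb, or 45.3% of the bases covered by either, and shifted T2D peaks overlapped at 15.1% to 15.9%. T2D peaks without a partner had a median enrichment of 6.13 against 7.05 for matched peaks, and control peaks 6.18 against 7.14. The share without a partner fell from 56.5% in the weakest to 2.72% in the strongest 10% of the T2D list and from 55.9% to 3.06% in the control list. Among the strongest 0.1%, 0 of 179 T2D and 0 of 178 control peaks lacked a partner, which allows shares of up to 1.68% and 1.69%.

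The 6 most enriched T2D-only sperm regions had enrichments of 15.27 to 16.62 with 53 to 69 tags, and 3 of them lay on chromosome 14. The first, on chromosome 16 from 65791707 to 65792293 (16.62, 69 tags), had peaks in both islet libraries. The chromosome 14 regions ran from 46837954 to 46838814 (16.37, 59 tags, a peak in control islets), from 36157248 to 36157982 (16.12, 59 tags) and from 30031982 to 30032524 (15.71, 53 tags), the last pair without an islet peak. On chromosome 7, the region from 81793156 to 81794418 (15.36, 66 tags) had peaks in both islet libraries and that from 110201039 to 110201525 (15.27, 54 tags) had none. The 6 most enriched control-only regions had enrichments of 14.34 to 15.68 with 48 to 112 tags. Of these, chromosome 5 from 9722835 to 9723814 (15.68, 55 tags), chromosome 1 from 45791981 to 45792684 (15.66, 56 tags), chromosome 8 from 126080549 to 126081057 (14.76, 48 tags) and chromosome 13 from 16785085 to 16785687 (14.34, 59 tags) had no islet peak. Chromosome 7 from 66885424 to 66886044 (14.63, 52 tags) and chromosome 5 from 22459281 to 22460616 (14.45, 112 tags) had peaks in both islet libraries.

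Islet and sperm lists overlapped less with each other than the lists of the same tissue did between conditions. Of the T2D islet peaks, 58.0% (57.7% to 58.2%) overlapped a T2D sperm peak, and 59.2% (59.0% to 59.5%) of control islet peaks overlapped a control sperm peak. In the other direction the shares were 54.2% for T2D and 55.8% for control sperm. Of the 307174 union regions, 65916 (21.5%) were present in all 4 libraries, 25758 (8.39%) in both islet libraries and neither sperm library, and 27868 (9.07%) in both sperm libraries and neither islet library. The background estimated from the enrichment values was 2.41 and 2.45 tags in islets and 3.25 and 3.26 tags in sperm.

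**Figure D2:**
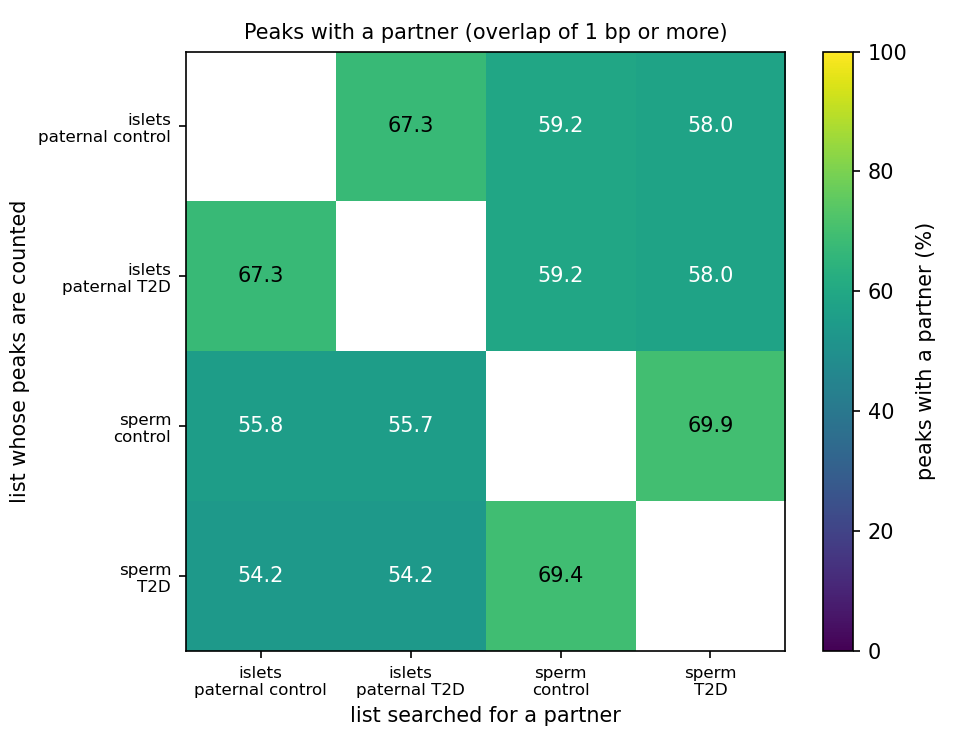
Percentage of the peaks of each list (rows) that overlap a peak of another list (columns) by at least 1 bp, shown by colour and as a number. The pairs of conditions within a tissue lie between 67.3% and 69.9% and the pairs of tissues between 54.2% and 59.2%.

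The X chromosome stood apart in the comparison of tissues. Sperm came from males alone and the labels do not give the sex of the offspring. Sex and tissue therefore cannot be told apart in the X values. Peaks on X made up 1.92% and 2.08% of the control and T2D islet lists but 1.01% and 0.971% of the sperm lists. Of the X peaks of control islets, 34.7% (33.0% to 36.3%) were also found in T2D islets and had no peak within 1000 bp in either sperm library, against 12.4% of autosomal peaks. In T2D islets the values were 32.1% (30.6% to 33.7%) and 12.4%. In the opposite direction, control sperm peaks also found in T2D sperm and absent from both islet libraries were counted. They made up 14.1% (12.6% to 15.8%) of X and 13.2% of autosomal peaks. More X than autosomal peaks of control sperm lacked a partner in T2D sperm (42.4% against 30.0%). The shares therefore do not compare absence from islets among peaks found in both sperm libraries. In the strongest 1% of control sperm, 35 of 333 peaks absent from islets lay on X, against 26 of 1441 peaks present there.

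How absence from the other tissue varied with score also differed between tissues. The share of islet peaks absent from both sperm lists declined over successive 10% of the list by score, from 35.9% in the weakest to 16.0% in the strongest 10% of the control list, and was 13.1%, or 22 of 168 peaks, in the strongest 0.1%. The share of control sperm peaks absent from both islet lists declined from 42.5% to 8.78%, but rose again to 18.8% in the strongest 1% and to 56.7% (49.4% to 63.8%) of 178 peaks in the strongest 0.1%. T2D sperm gave 59.2% (51.9% to 66.2%), or 106 of 179 peaks. In either sperm library, 100% of these strongest peaks had a partner in the other sperm library. The 3 highest-scoring sperm regions absent from islets were chosen after their values were seen. The first lay on chromosome 3 from 14983336 to 14984181, with 608 tags in control and 605 in T2D sperm. It was followed by X from 97100841 to 97101430, with 455 and 454 tags, and chromosome 2 from 107887472 to 107888072, with 482 and 503 tags. The highest-scoring islet regions absent from sperm, chosen in the same way, held fewer tags, with 170 and 189 on chromosome 8 from 23518231 to 23519259 and 121 and 109 on chromosome 4 from 95293946 to 95294773. Tag counts were not scaled to depth, which is unknown for islets, so they do not compare strength between tissues.

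**Figure D3:**
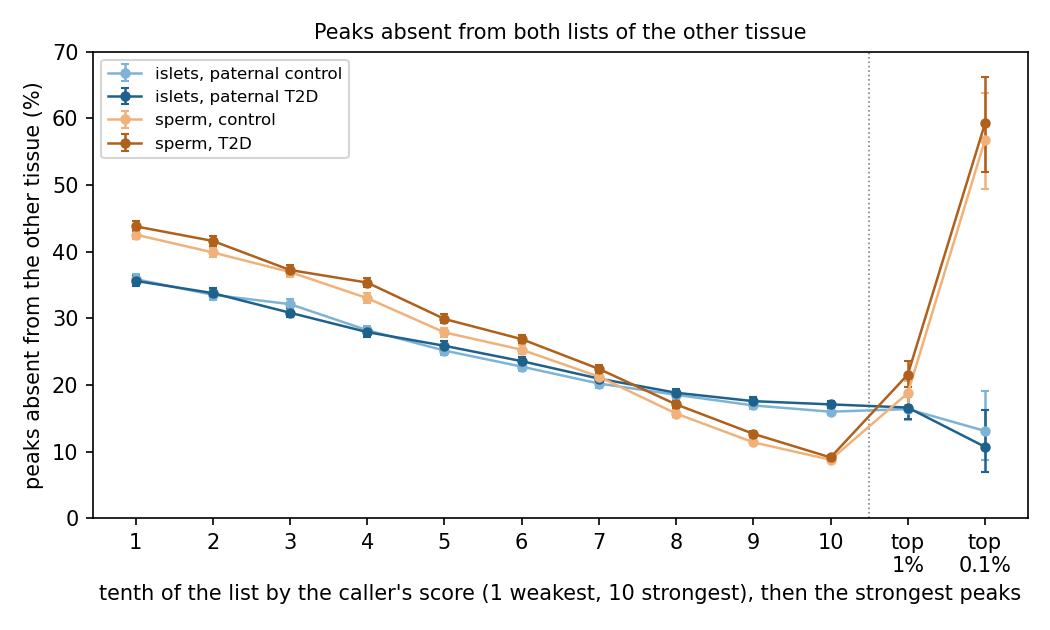
Percentage of peaks (y axis) with no peak within 1000 bp in either library of the other tissue, by successive 10% of each list ranked on the caller's score (x axis), followed by the strongest 1% and 0.1%, with 95% Wilson intervals for counting error. Both sperm libraries rise in the strongest 0.1%, to 56.7% and 59.2%, while the islet libraries stay at 13.1% and 10.7%.

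Whether the same regions differed in the same direction in sperm and in offspring islets was then counted. In islets, 53796 union regions were T2D only and 53889 control only, and in sperm 54316 and 53034. A total of 27403 regions differed in both tissues, of which 6853 were T2D only in both, 6914 control only in both, 6744 T2D only in islets but control only in sperm, and 6892 the reverse. The direction was thus the same in 13767 regions, or 50.2% (49.6% to 50.8%), and opposite in 13636, with an odds ratio of 1.02. Independent directions among these regions would put 6820 regions at T2D only and 6881 at control only in both tissues. Over all union regions, independent statuses would give 9512 and 9304; every union region was called in at least 1 library, which ties the statuses together. The tissues share no control library. Among the peaks of the best 10% by score with no partner within 1000 bp, 552 T2D-only and 512 control-only islet peaks met 460 T2D-only and 502 control-only sperm peaks in 10 overlaps, 4 of them in the same direction (40%, interval 16.8% to 68.7%).

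**Figure D4:**
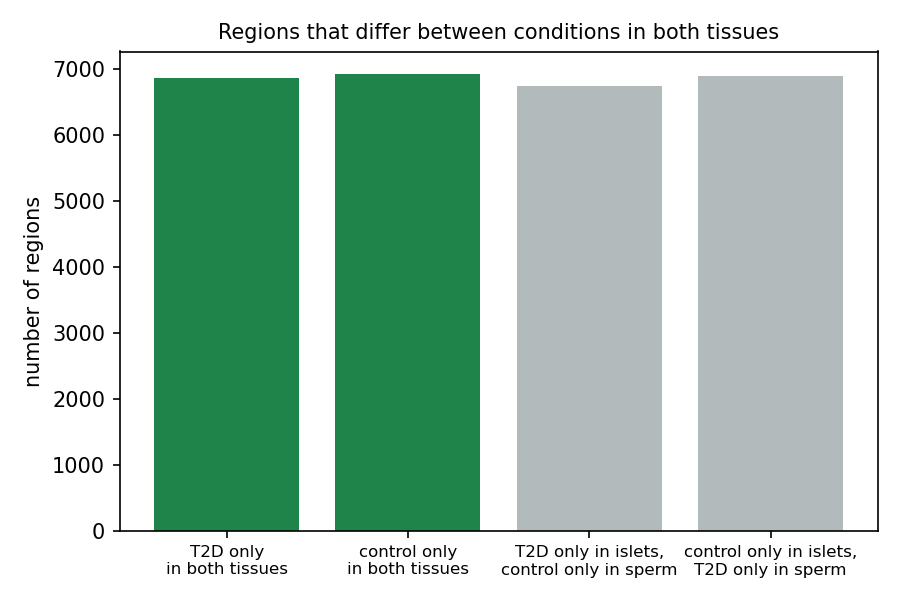
Number of union regions (y axis) that were called in a single condition in islets and in a single condition in sperm, by direction. The same-direction classes (green, 6853 and 6914) and the opposite-direction classes (grey, 6744 and 6892) are of similar size.

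Among regions with the same status in both tissues, those of T2D only were led by chromosome 6 from 133752093 to 133752779, with an enrichment of 12.92 in islets and 12.45 in sperm. Then came chromosome 11 from 64198756 to 64199473 (12.30 and 13.80), chromosome 18 from 59482712 to 59483714 (12.28 and 12.25), chromosome 12 from 10937603 to 10938282 (12.40 and 11.25), chromosome 9 from 89260564 to 89261241 (11.81 and 11.43) and chromosome 1 from 22504105 to 22505016 (11.60 and 11.92). Control-only regions were led by chromosome 12 from 60733538 to 60734006 (12.86 and 12.59), chromosome 6 from 71234360 to 71234902 (12.06 and 12.30) and chromosome 8 from 107540422 to 107540923 (12.06 and 14.25). The next were chromosome 18 from 71483010 to 71483821 (11.89 and 11.20), chromosome 6 from 148846537 to 148847403 (11.75 and 14.15) and chromosome 7 from 96282443 to 96283398 (11.64 and 11.07). Coordinates are those of the islet peak. The regions were picked from 5938 T2D-only and 5847 control-only candidates, and none of opposite direction was named. In islets the T2D-only regions held 30 to 66 tags and the control-only regions 29 to 42, against a list median of 39. In sperm they held 44 to 60 and 39 to 70 tags, against a list median of 50.

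Condition-specific peaks made up similar shares of every autosome. The share without a partner ranged over the 19 autosomes from 31.5% on chromosome 18 to 34.0% on chromosome 14 in T2D islets, and from 28.9% on chromosome 19 to 31.6% on chromosome 12 in T2D sperm. It was higher on X, at 39.9% (38.3% to 41.5%) in T2D islets, 35.2% (33.6% to 36.9%) in control islets, 40.5% (38.3% to 42.9%) in T2D sperm and 42.4% (40.1% to 44.7%) in control sperm. Among the best 50% of control islet peaks by score the difference was small, with 39.7% on X and 39.3% on autosomes. The share on X stayed higher in the best 50% of T2D islets (43.7% against 39.1%), T2D sperm (45.8% against 37.9%) and control sperm (43.8% against 37.4%). T2D islets had 3478 X peaks against 3222 in control islets, a ratio of 1.08 (exact interval 1.03 to 1.13), whereas autosomal peaks gave a ratio of 0.996 (0.989 to 1.00). In sperm the ratio for X peaks was 0.969 (0.906 to 1.04). Y peaks numbered 32 in control and 23 in T2D islets, a ratio of 0.719 (0.402 to 1.27), and 27 and 26 in sperm. The labels do not give the sex of the offspring.

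**Figure D5:**
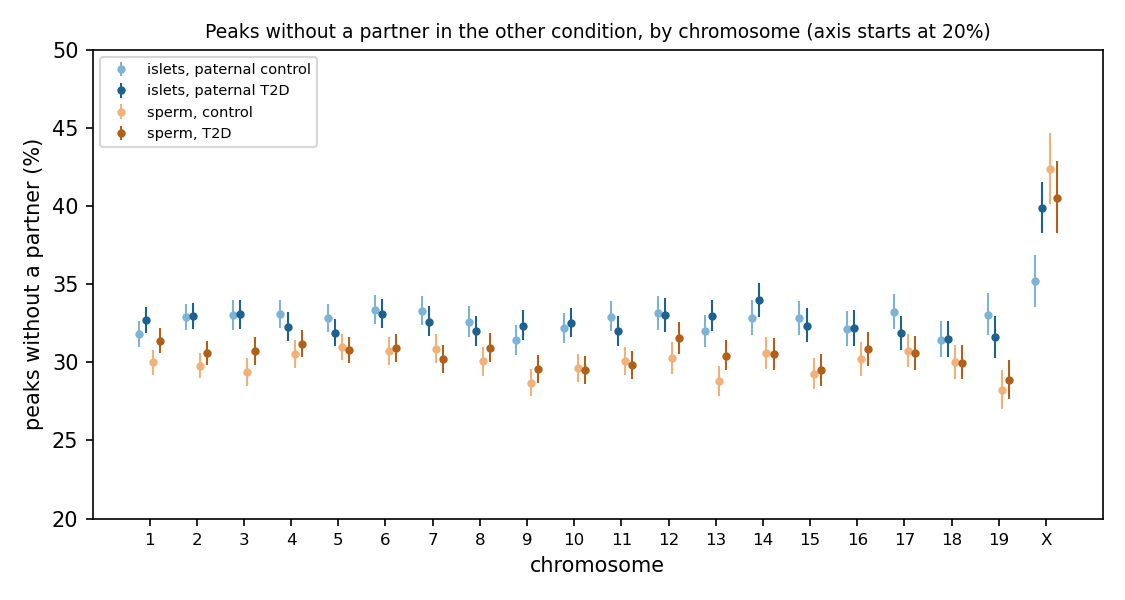
Percentage of peaks without a partner in the other condition (y axis, starting at 20%) for chromosomes 1 to 19 and X (x axis) in each of the 4 libraries, with 95% Wilson intervals for counting error. Autosomes lie between 28.3% and 34.0% and X lies above them in each library, at 35.2% to 42.4%.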

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

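The tests of explanations in this part were chosen only after the results were seen, as was the restriction of X peaks to the best 50% by score. With 1 library per group, none of the differences named next between tissues was tested.

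The number of X peaks moved in opposite directions in the tissues, with 256 more in T2D than in control islets while in sperm it decreased by 56. In the best 50% of each list, an alternative chosen after seeing the data, the T2D to control ratio was 1.07 in islets, with an interval that, unlike that of all peaks, includes 1, and turned from 0.969 to 1.04 (0.943 to 1.15) in sperm, where both intervals include 1. A deeper T2D library is argued against, since autosomal peaks gave a ratio of 0.996, below the interval of the X ratio. A candidate explanation is a larger share of female offspring in the T2D islet sample: X tags in matched peaks, relative to all matched peaks, gave a T2D to control ratio of 1.05 (1.04 to 1.06), and Y tags gave 0.911 (0.823 to 1.01), an interval that includes 1. In sperm, which came from males alone, X tags gave 1.01 (1.00 to 1.03), also above 1, and Y tags gave 1.15, with a lower bound of 1.06, so both measures vary between libraries by more than counting error and the sex of the offspring and an effect of the father's condition cannot be told apart.

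The number of peaks fell by 387 from control to T2D islets and rose by 1242 from control to T2D sperm, but among peaks with an enrichment of at least 7.03 the sperm number was lower in T2D (78583) than in control (81650). Covered length was 5.91 Mb greater in T2D than in control islets and, in sperm, decreased by 0.0708 Mb. With the same enrichment filter the islet length turned to 80.5 Mb in T2D against 82.8 Mb in control. The filtered sperm length was 76.4 Mb in T2D against 80.8 Mb in control, so both tissues were then lower in T2D. Median peak width was 33 bp greater in T2D than in control islets and, in sperm, decreased by 9 bp.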

How the results depend on the processing

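The share of T2D islet peaks with a control partner (67.3%) became 62.9% with a reciprocal overlap of 50%, 70.3% with partners within 1000 bp and 60.8% for the best 50% of each list. The share of T2D sperm peaks with a control partner (69.4%) became 65.0%, 72.7% and 62.1% in that order, and 68.9% at equal list lengths. The share of T2D islet peaks with a T2D sperm partner (58.0%) became 51.8%, 63.4% and 47.6%, then 55.8% at equal list lengths and 58.7% on autosomes. It stayed below the islet overlap between conditions under each of these settings. Restricting both lists to their best 50% removes weak partners of strong peaks and so can lower the overlap. The share of X peaks of T2D islets without a partner (39.9%) became 43.7% for the best 50%, while that of autosomal peaks rose from 32.5% to 39.1%. The share of regions with the same direction in both tissues was 50.2% to 50.7% under the 5 alternatives, and with partners within 1000 bp its interval was 50.1% to 51.2%. With an enrichment of at least the median of all lists (7.03), the peak numbers became 95424 in control and 90299 in T2D islets and 81650 in control and 78583 in T2D sperm, so the islet lists, shorter as deposited, became the longer ones. Enrichment is relative to each library, so this filter does not put the tissues on the same scale. Differences between conditions turned direction in several places. Under this filter the T2D sperm list became shorter than the control list and the covered length of T2D islets (80.5 Mb) fell below that of control islets (82.8 Mb). In the best 50%, the share of X sperm peaks without a partner turned from lower to higher in T2D (45.8%, control 43.8%), as did the ratio of X peaks in sperm. The number of islet peaks without a partner, as deposited slightly lower in T2D, became higher with partners within 1000 bp (49724, control 49626) and at equal list lengths (54829, control 54618). At equal list lengths the number of sperm peaks without a partner became lower in T2D (52007, control 52011). The cause of these turns was not tested. Of 60 values recomputed beside the main comparisons, among them several of those just named, 29 stayed within their counting interval or, for counts, within a fixed factor, and 31 moved. The regions named within a tissue were chosen for having no partner within 1000 bp, so the settings do not test them. A call in only 1 list says little about a region near the caller's threshold, and the part played by depth there was not tested. No leave-one-out was possible with 1 library per group. No paired analysis was possible because the labels carry no shared replicate numbers. The alternatives for promoter windows, transcript starts and gene lists were not run, because no annotation on mm9 was used.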

Other observations

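The tests in this part were chosen only after the results were seen, except the share of regions with the same direction in both tissues, which was planned but used as a test of an explanation only afterwards. Whether condition-specific peaks gathered in parts of the genome was tested. Counted in windows of 1 Mb with at least 20 unmatched peaks, the difference between T2D-only and control-only islet peaks, divided by the square root of their sum, reached at most 4.02 and at least -3.69 over 2216 windows. In 1000 shuffles of the condition labels over the unmatched peaks, the 99th percentile of the highest value was 4.24 and the corresponding lower limit was -4.26. In sperm the extremes were 3.75 and -3.50 over 2123 windows, with shuffled limits of 4.28 and -4.24. No single window in either tissue passed these limits, but over all windows the values spread slightly more than in the shuffles. Their SD was 1.06 in islets, above the highest of the 1000 shuffles (1.04), and 1.03 in sperm, where 11 of 1000 shuffles gave an SD as high. Neighbouring peaks are not independent, and the shuffles treat them as if they were. Mitochondrial peaks numbered 2 in control sperm, 1 in T2D sperm and 0 in either islet library.

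The large number of peaks specific to 1 condition invites 3 readings. Calls near the detection threshold are a candidate explanation, because the share without a partner was 3.47% in the best 10% of T2D islet peaks by score and 58.7% in the weakest 10%. A difference in depth between the conditions is another reading. In islets the numbers on both sides were near equal, with a T2D to control ratio of 0.997. These numbers follow the list lengths (167325 T2D and 167712 control peaks), and islet depth is unknown, so they cannot decide on depth. The same change in both tissues at most of these regions is argued against, since 50.2% (49.6% to 50.8%) of the regions that differed in both tissues had the same direction. An effect of the father's condition at a smaller number of regions, or at different regions in each tissue, stays open, since a single library per group cannot separate it from variation between animals or libraries.

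More sperm than islet peaks had very high scores, with 328 and 353 peaks above a score of 500 in control and T2D sperm against 39 and 33 in islets. Scores are relative to each library and the islet caller settings are unknown, so these counts are not on the same scale. Most of the strongest 0.1% of sperm peaks were absent from islets. An artefact of a single sperm library is argued against, since 100% of such peaks of control sperm were found in T2D sperm. A greater depth of the sperm libraries is argued against as the whole cause, since lower depth in islets loses peaks with fewer tags first. The share absent from islets was 8.78% in the best 10% of control sperm peaks and 56.7% in the strongest 0.1%. The absent strongest peaks held a median of 188 tags against 83 for the best 10% found in islets, though these classes differ in score. Within the strongest 0.1%, absent peaks held fewer tags than those found in islets, with medians of 188 against 264 in control sperm. T2D sperm gave 189.5 against 280. Absent peaks were also narrower, with medians of 589.5 bp against 841 bp in T2D sperm, and tags were not adjusted for width. The tag medians therefore do not show absent peaks to be weaker, and a part played by depth stays open. The largest depth difference the lists allow is a factor of 0.241, as if every control islet tag lay in a peak. Scaled by it, 100% (96.3% to 100%) of the absent strongest control sperm peaks would keep at least the lowest tag count of a control islet peak (18). The weakest of them would keep 19.1 tags. The median (39) would be kept by 60.4% (50.6% to 69.4%). The count needed for a call at these positions is unknown, so this does not show that they would be called. Stacking of reads from multicopy sequence might contribute, since 9.90% (5.47% to 17.3%) of the absent strongest control sperm peaks lay on X against 1.01% of the whole list. Of the 77 equally strong peaks shared with islets, 10.4% (5.36% to 19.2%) also lay on X. In the strongest 1%, however, X held 35 of 333 absent and 26 of 1441 shared peaks of control sperm. T2D sperm gave 39 of 385 and 35 of 1401. Within the strongest 0.1% of control sperm, absent peaks were narrower than shared ones (medians of 602 bp against 865 bp) and more enriched (16.43 against 14.42). The lists hold no sequence, so read stacking and methylation specific to sperm cannot be told apart here.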
